A study of Mus musculus with 2 samples.

How the data were processed

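The series holds 2 samples of mouse primary rib chondrocytes, 1 Sox6 ChIP and 1 input DNA, and 2 peak lists. Per the labels' protocols, ribs of postnatal day 1 ICR mice were dissected to keep proliferative and prehypertrophic cartilage, the cells were fixed in 1% formaldehyde, and the chromatin was sheared to 100 to 600 bp. Bowtie and the mouse genome build mm9 are named, without versions, per the submitters' processing notes for these samples. The peak caller, its threshold and any filter on peaks are not given in the sources used here, although the names of both lists carry the mark FDR without further explanation. Per the series' design text, the Sox9 list is a third-party re-analysis of 2 earlier samples of Sox9 ChIP-seq in the same cell type, called in the manner of the Sox6 list. Which of these samples were ChIP or input, whether any were pooled, and the strain and age of the animals are not given in the sources used here, nor is a genome build for this list alone. It was taken as mm9 because 76.7% of its peaks overlap a Sox6 peak, against 1.17% by chance. The Sox9 data were made separately, so a difference between the lists can come from the antibody, the strain or age of the animals, the depth or the library as well as from the factor.

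Each list as deposited by the authors has 3 columns without a header: chromosome, start and end of a called peak. There are no scores, fold enrichments, p-values or read counts, so no peak was tested against input here and depth cannot be stated. Starts were read as BED starts, counted from 0, and are printed counted from 1. Neither list has duplicate peaks. In the Sox6 list 580 neighbouring peaks overlap each other, and 148 in the Sox9 list, and these were kept as called. On 9 of 21 chromosomes a peak lies beyond the last gene of the GRCm38 gene table used here, which can happen in any build. This check does not settle the build, which was taken from the submitters' notes. No mm9 genome or annotation was used, coordinates were not converted, and the planned shares of peaks at promoters, tests of gene lists, counts of peaks per gene and SOX motif counts were not run.

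A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Chance was estimated by moving all Sox9 peaks of a chromosome by 1 random distance, wrapped within the range between the first and last peak of the chromosome, 1000 times. Local shifts moved each peak separately by 20000 to 200000 bp in a random direction. One-sided permutation p-values count shifts with at least the observed overlap. These tests treat called peaks as fixed and say nothing of the variation between animals or libraries. Clusters were runs of peaks of 1 list with neighbouring centres within 12500 bp, compared with 1000 sets of uniform positions with the same number per chromosome. Clustered and single peaks were compared by permuting overlap over peaks 1000 times, or within 20 bins of list position. These permutations treat peaks as independent, which peaks of 1 cluster are not, so their SDs and p-values may be too small. Exact binomial intervals (Clopper-Pearson, 95%) cover counting error only, and they treat peaks as independent, which clustered peaks are not.

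The design, the alternatives and the rule for naming regions were fixed before the data were examined. The rule named the 10 Sox6 clusters with the most shared peaks and the first 5 peaks of each list, since no gene could be placed. The planned test of rank by score was run on position in the deposited list, because no score exists. That order was taken as a ranking only after overlap had been seen to fall along it, which also holds for the alternatives that take the first part of a list. The alternatives were an overlap of 50% of both peaks, centres within 250 bp, a gap of up to 1000 bp, the first 50% of each list, equal list lengths, the first 2000 peaks, local shifts, autosomes only, rank by width, and cluster gaps of 5000 and 25000 bp. Comparisons of clustered with single peaks, the test of each dense cluster, distances and centre offsets, the X comparisons between lists and of shared peaks, equal list lengths for chromosome X and the removal of 1 X cluster were added after seeing the data.

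The tests were first tested on simulated lists of 23865 peaks, with 200 shifts or draws for the overlap and cluster tests and 1000 permutations for the others. With 40% of simulated peaks placed on Sox6 peaks the excess overlap came out at 39.96%, with 2% placed at 2.01%, and with none placed the overlap was 0.891 of chance (p = 0.97, permutation). With 300 clusters planted, 252 clusters above chance were found, and with none, 1.66. A built-in difference of -6 percentage points between clustered and single peaks was recovered as -5.67. Apart from planted ones, simulated peaks were placed uniformly, and for the comparison of clustered with single peaks overlap was drawn independently for each peak. The simulations therefore do not show how the tests behave on clustered lists like these. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.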

Results

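The data describe where 2 SOX transcription factors were called as bound in primary rib chondrocytes of mice. SOX9 is the HMG-box factor required for cartilage formation, and SOX6 is a related HMG-box factor of the SOXD group that acts with it in chondrocytes. One chromatin immunoprecipitation (ChIP-seq) sample used an antibody to Sox6, and 1 sample of input DNA without antibody came from the same kind of cells, taken at postnatal day 1 from ICR mice. The second peak list holds Sox9 peaks, which the authors derived again from earlier ChIP-seq samples of mouse rib chondrocytes and called in the same way as the Sox6 peaks. The strain and age of the animals behind the Sox9 list are not given in the sources used here and may differ. The Sox6 list held 79107 peaks with a median width of 151 bp, and the Sox9 list held 23865 peaks with a median width of 183 bp. Peak widths summed to 13.4 Mb for Sox6 and 4.61 Mb for Sox9, with sequence in overlapping neighbours counted more than once. There is 1 list per factor and no replicate, so no value below carries a replicate error, and the intervals cover counting error only. The lists give positions without read counts or scores, and sequencing depth is unknown. The series is titled for an Indian hedgehog enhancer of chondrocytes. The Ihh locus and all other genes were not analysed here, because the gene tables used here are on another genome build than the peaks, and regions are therefore given by mm9 coordinates.

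The first comparison asked how far Sox6 and Sox9 were called at the same sites. Most Sox9 peaks touched a Sox6 peak: 18302 of the 23865 Sox9 peaks, or 76.7% (95% exact binomial interval 76.1 to 77.2), overlapped a Sox6 peak by at least 1 bp. The reverse share was smaller, in a list 3.31 times as long. Of the 79107 Sox6 peaks, 18237 overlapped a Sox9 peak, which is 23.1% (22.8 to 23.3), and 60870 Sox6 peaks and 5563 Sox9 peaks had no counterpart. When the Sox9 peaks were moved at random along their chromosomes, 278 ± 18.9 of them (SD over 1000 shifts) met a Sox6 peak, so that the observed number was 65.8 times the chance value (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). Against local shifts, which moved each peak separately by 20000 to 200000 bp, the excess was 32.5-fold with the same p. Neither kind of shift keeps peaks on open chromatin or on mappable sequence. The folds are therefore not shown to be specific to these factors. The shares moved with the overlap required and the part of each list that was used. With 50% of both peaks required to overlap, 44.6% of Sox9 peaks and 13.4% of Sox6 peaks were shared. With the first 23865 Sox6 peaks against all Sox9 peaks, 49.9% of the Sox6 peaks and 50.3% of the Sox9 peaks overlapped. Among the first 2000 peaks of each list, 664 Sox6 peaks (33.2%) met 1 of the first 2000 Sox9 peaks, against 0.57 by chance.

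Overlap fell steeply along the Sox6 list and more gently along the Sox9 list. The Sox6 list is 3.31 times as long, so most of its peaks cannot each have a Sox9 peak of their own. The falls were not compared at equal list lengths, so their difference in steepness is not shown to lie in the factors. As wholes the lists are not sorted by position in the genome, and their order is not documented. Late in the Sox6 list some consecutive places follow the genome, such as places 75772 to 75775 in 1 cluster on chromosome 3. The order was treated as a ranking only after overlap had been seen to fall along it. The tests of list position therefore describe that fall and are not independent evidence for it. Pairs were taken as each Sox9 peak with the Sox6 peak of nearest centre, where these overlapped, so other overlaps were left out. Over the 18297 such pairs the order of the Sox6 list went with that of the Sox9 list (Spearman rho 0.37, Pearson r 0.32). The permutation p was 0.001, the smallest that 1000 permutations can give. The pairs are sites within 1 pair of lists and not independent replicates, and a Sox6 peak can belong to more than 1 pair. Of the first 5% of Sox6 peaks, 78.3% (77.0 to 79.6) overlapped a Sox9 peak, and of the last 5%, 4.68% (4.04 to 5.38). The last 5% still lay above the 0.724% that local shifts gave. In the Sox9 list the share fell from 90.6% (88.8 to 92.2) in the first 5% to 64.7% (61.9 to 67.4) in the last 5%. The median position of shared Sox6 peaks was at 19.4% of the list, against 58.6% for unshared ones, and the corresponding Sox9 values were 45.4% and 63.7% (two-sided permutation test, p = 0.0001 for each list, the smallest that 10000 permutations can give). The first 5 Sox6 peaks and the first 5 Sox9 peaks all overlapped the other list. The first Sox6 peak lay on chromosome 17 from 26719377 to 26719510, and its centre was 52.5 bp from that of a Sox9 peak. The second lay on chromosome 10 from 121341251 to 121341375, the third on chromosome 14 from 27489171 to 27489416, the fourth on chromosome 10 from 67817656 to 67817778 and the fifth on chromosome 9 from 78471314 to 78471498. The first Sox9 peak lay on chromosome 15 from 12123969 to 12124135, with a Sox6 centre 36.5 bp away. It was followed by peaks on chromosome 17 from 79698273 to 79698447, chromosome 5 from 115495299 to 115495458, chromosome 14 from 31074905 to 31075178 and chromosome 1 from 174238120 to 174238295. Ordering the Sox6 peaks by width in place of list order removed the difference between shared and unshared peaks (medians at 50.5% and 49.8%, permutation p = 0.347), and for Sox9 it left a smaller one (48.5% and 56.1%, permutation p = 0.001).

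**Figure D1:**
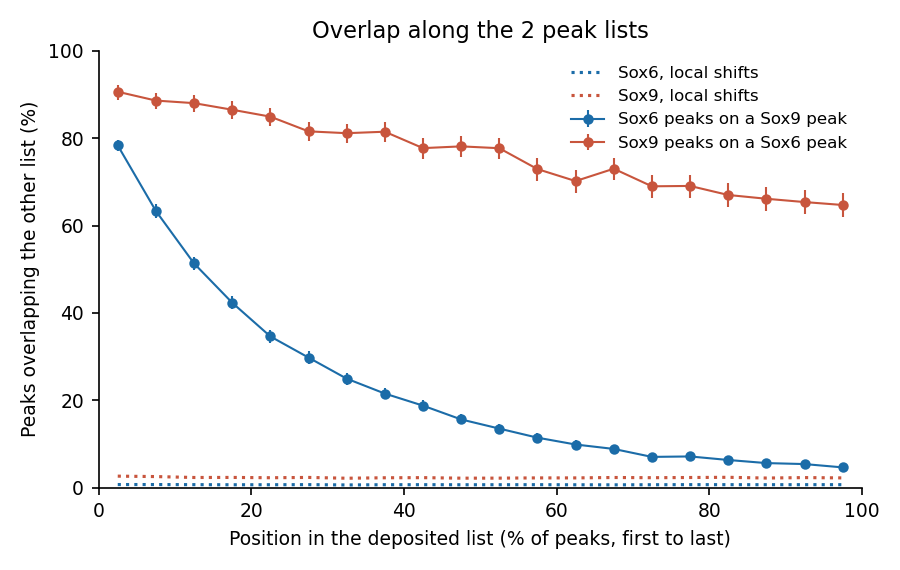
Share of peaks overlapping the other list (vertical axis, %) in 20 consecutive bins of list position (horizontal axis, % of the list), with 95% exact binomial intervals as bars and the mean of 100 sets of local shifts as dotted lines. The Sox6 curve falls from 78.3% to 4.68% and the Sox9 curve from 90.6% to 64.7%. The lists differ in length, and the curves were not compared at equal lengths.

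Where the peaks of the factors overlapped, their centres were closer together than those of pairs that met by chance. The centres of the 18297 overlapping pairs of a Sox9 peak with its nearest Sox6 centre were a median of 40.5 bp apart (quartiles 18 and 76.5 bp). Of these pairs 58.5% (57.8 to 59.2) were within 50 bp. Pairs that met by chance under local shifts were a median of 89.5 ± 3.98 bp apart (SD over 100 shifts), with 28.3% within 50 bp. These shifts do not keep peaks on open chromatin either, so the closeness of centres is not shown to be specific to these factors. Peaks without a counterpart lay closer to the other factor than chance gave, and most of the Sox9 ones were near a Sox6 peak. Among the 5563 Sox9 peaks that overlapped no Sox6 peak, 58.8% (57.5 to 60.1) had a Sox6 centre within 1000 bp, against 8.81% under local shifts (one-sided permutation test, p = 0.001, the smallest possible). Their median distance to a Sox6 centre was 645 bp, against 8538 bp by chance. The 60870 unshared Sox6 peaks lay farther from Sox9, at a median of 15935 bp against 27345 bp by chance, and 10.3% (10.1 to 10.6) were within 1000 bp of a Sox9 centre against 2.90% by chance (permutation p = 0.001). With a gap of up to 1000 bp allowed between peak edges, 90.8% of Sox9 peaks had a Sox6 peak beside or on them.

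**Figure D2:**
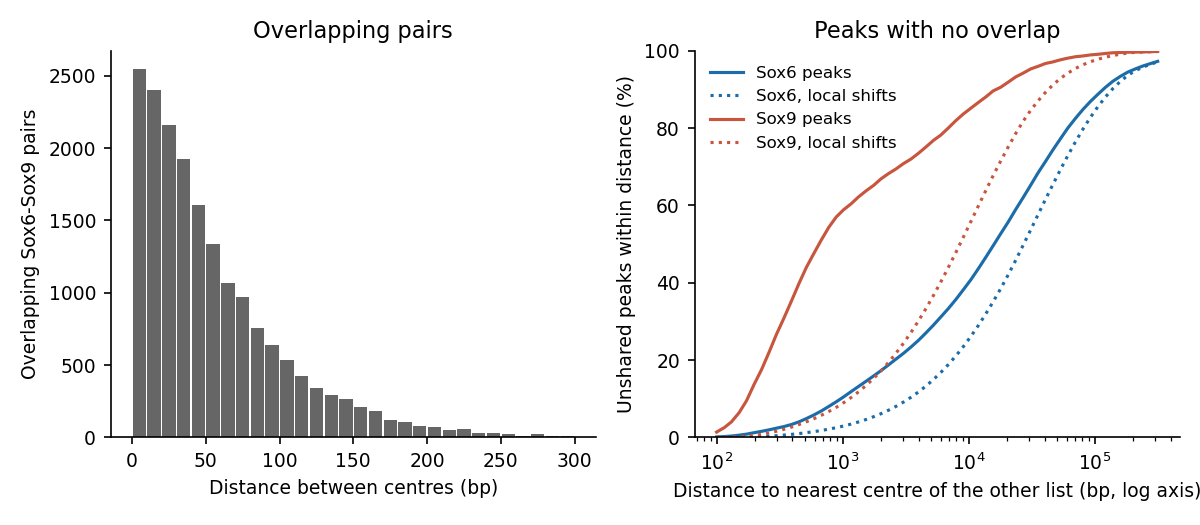
Left, number of overlapping Sox6 and Sox9 pairs (each Sox9 peak with its nearest Sox6 centre) by the distance between their centres in bins of 10 bp. Right, cumulative share (%) of the unshared peaks of each list within a given distance of the nearest centre of the other list (bp, log axis), with local shifts dotted; 58.8% of unshared Sox9 peaks lie within 1000 bp of a Sox6 centre against 8.81% by chance.

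Peaks of both factors were gathered in clusters, here runs of 3 or more peaks of 1 list with neighbouring centres no farther apart than a distance set before the data were examined. The Sox6 list formed 9068 such clusters with 62.9% of its peaks, against 26.0% of uniformly drawn positions. The Sox9 list formed 1796 clusters with 30.5% of its peaks, against 3.82% (one-sided permutation tests, p = 0.001 for each, the smallest that 1000 draws can give). Uniform draws ignore unmappable sequence and uneven gene density, so these ratios describe departure from evenness only. The 10 Sox6 clusters with the most shared peaks spanned 34.3 to 209 kb and held 601 Sox6 peaks, of which 161 overlapped a Sox9 peak. The largest lay on chromosome 10 from 82438607 to 82647670, with 111 Sox6 peaks and 30 Sox9 peaks, and 23 of its Sox6 peaks were shared. A cluster on chromosome 7 from 124521848 to 124684205 held 79 Sox6 and 28 Sox9 peaks with 22 shared. On chromosome 4 from 62820119 to 63004733 there were 106 Sox6 and 28 Sox9 peaks with 21 shared, including the Sox6 peak at place 14 of the list. The cluster on chromosome 3 from 27413225 to 27609433 had 100 Sox6 peaks, of which 17 were shared. The 3 shortest of the 10 clusters had the highest shared proportions. The choice of clusters by number of shared peaks favours this, since a cluster with few peaks needs a high proportion to enter. On chromosome 15 from 97833647 to 97887558, 14 of 22 Sox6 peaks were shared, and on chromosome 2 from 145550847 to 145634256, 13 of 18 were. The remaining 4 lay on chromosome 6 from 37276637 to 37403389, on chromosome X from 166412440 to 166446723, on chromosome 11 from 117055816 to 117180947 and on chromosome 13 from 45891760 to 46070271, with 12 or 13 shared peaks each. The X cluster lies near the end of that chromosome, and whether repeats or sequence shared with chromosome Y affect the peaks called there was not tested.

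**Figure D3:**
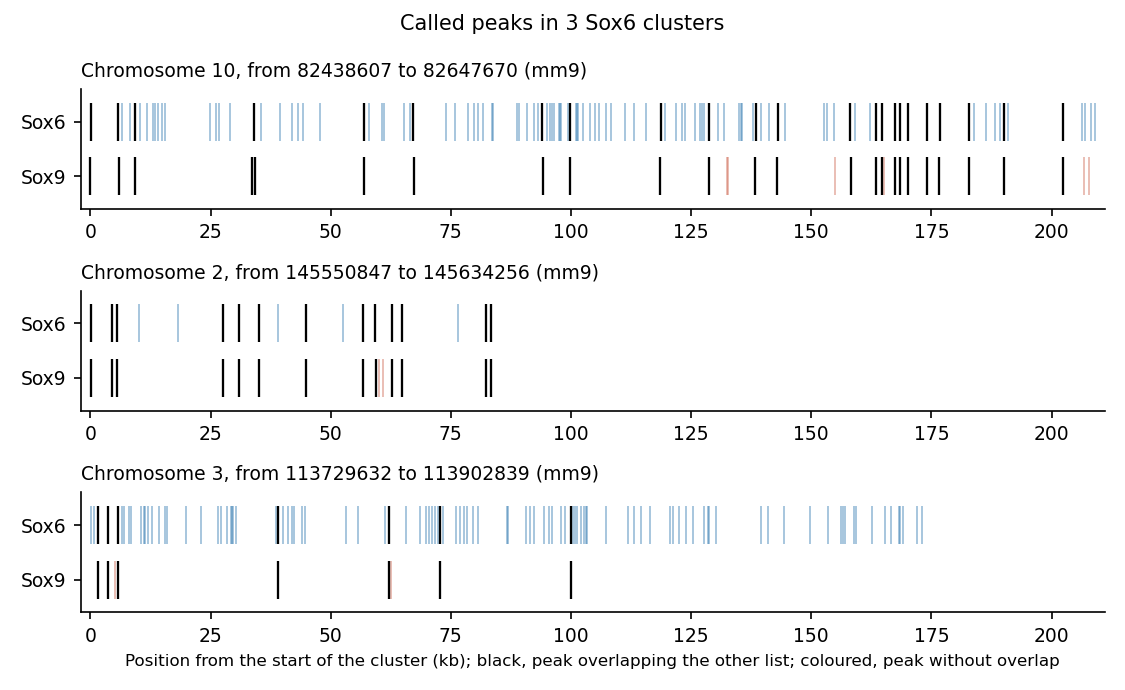
Called peaks along 3 Sox6 clusters (horizontal axis, kb from the start of the cluster, mm9), with Sox6 peaks in the upper row and Sox9 peaks in the lower row of each map, and peaks that overlap the other list in black. The chromosome 10 cluster holds 111 Sox6 peaks with 23 shared, the chromosome 2 cluster 18 with 13 shared, and the chromosome 3 cluster, chosen after its values were seen, 103 with 7 shared.

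Clustered and single peaks, compared only after the overlap of clusters had been seen, differed in overlap for Sox9. Single Sox9 peaks overlapped a Sox6 peak in 80.4% of cases (79.6 to 81.2), whereas those in clusters of 3 or more did so in 72.3%, a difference of -8.11 percentage points (permutation SD 0.661, two-sided permutation p = 0.001). The share was 66.1% (60.7 to 71.3) in Sox9 clusters of 10 to 19 peaks and 48.0% (38.0 to 58.2) over the 102 peaks of the 4 clusters with 20 or more. Those 4 clusters were named after their values were seen, and differences between them were not tested. The one on chromosome 15 from 97804275 to 97885963 held 32 Sox9 peaks, of which 13 were shared, and the one on chromosome 19 from 5786466 to 5850375 held 29 with 9 shared. On chromosome 10 from 82557126 to 82646550, 15 of 21 were shared, and on chromosome X from 166413775 to 166446710, 12 of 20. With a gap of up to 1000 bp allowed the difference turned to 2.05 percentage points in favour of clustered Sox9 peaks. Sox6 peaks overlapped a Sox9 peak in 23.1% of cases whether clustered or single (permutation p = 0.981), but within bins of list position the difference was -1.49 percentage points (permutation p = 0.001). With the gap of up to 1000 bp, 34.9% of clustered and 25.5% of single Sox6 peaks met a Sox9 peak, a difference of 9.43 percentage points (permutation p = 0.001). With the gap, 1 peak of the other list can count for several peaks of a cluster, but for no more than 1 single peak. The gap therefore favours clustered peaks in either list, and the direction of these differences is partly set by the rule. The permutations behind these SDs and p-values moved overlap over individual peaks, although the 7289 clustered Sox9 peaks lie in 1796 clusters. Peaks of 1 cluster are not independent, so the SDs and p-values may be too small. Whether the clustering difference itself differs between the lists was not tested.

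**Figure D4:**
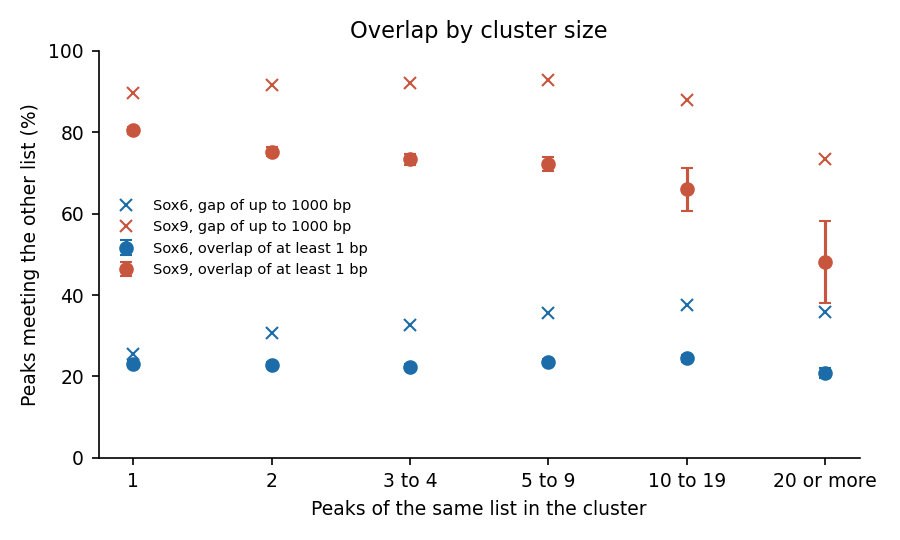
Share of peaks meeting the other list (vertical axis, %) by the number of peaks of the same list in their cluster, with filled points for an overlap of at least 1 bp (bars, 95% exact binomial intervals) and crosses for a gap of up to 1000 bp. The Sox9 share falls from 80.4% for single peaks to 48.0% in clusters of 20 or more, while the Sox6 share stays between 20.9% and 24.4%.

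Peaks of both factors were sparse on chromosome X. Sox6 peaks numbered 25.9 to 45.0 per Mb of peak range over the 19 autosomes, highest on chromosome 11, and 8.39 per Mb on X. The autosomes differed from each other as well (chi-square against their peak ranges 1289.5 for Sox6 and 465 for Sox9, as a description only). Sox9 peaks numbered 7.60 to 14.2 per Mb on autosomes, again highest on chromosome 11, and 1.52 per Mb on X. The density on X was 0.259 of the autosomal one for Sox6 (0.246 to 0.274) and 0.155 for Sox9 (0.136 to 0.175). Of the 245 Sox9 peaks on X, 75.5% (69.6 to 80.8) were shared, and 76.7% of those on autosomes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 2 tests, p = 0.649). Of the 1352 Sox6 peaks on X, 13.4% (11.6 to 15.3) were shared, against 23.2% on autosomes. With a like Sox9 share, this Sox6 difference follows from the numbers of peaks of the 2 lists on X and is not a separate finding. Each list held 5 peaks on chromosome Y, of which 1 was shared.

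**Figure D5:**
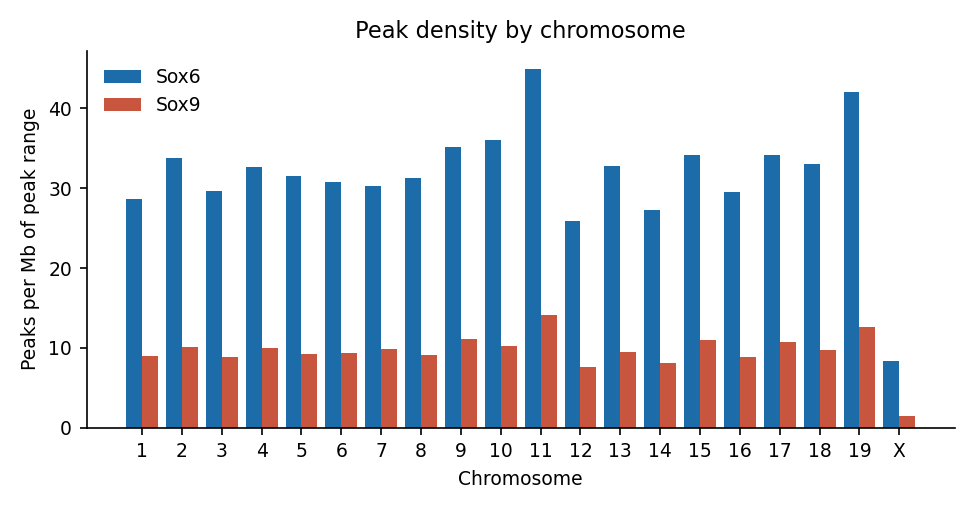
Peaks per Mb of the range between the first and last peak of each chromosome (vertical axis) for Sox6 and Sox9, chromosomes 1 to 19 and X. X has 8.39 Sox6 and 1.52 Sox9 peaks per Mb, below every autosome of the same list.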

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

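All tests in this part were chosen after the result was seen. The share of peaks on chromosome X differed between the lists: 1.71% of Sox6 peaks (1352) and 1.03% of Sox9 peaks (245) lay on X, an odds ratio of 1.68 (Fisher's exact test, two-sided, p = 6.20e-15). Peaks are counted here as independent, and the lists come from separate libraries. Length of the list may account for most of this: in the first 23865 Sox6 peaks the X share was 1.19% and the odds ratio 1.16 (Fisher's exact p = 0.0884), which does not show that the shares are equal. Without the dense cluster near the end of X the odds ratio of the full lists was 1.79. This removal was not run at equal list lengths, and taking the first Sox6 peaks relies on the undocumented order of the list.

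The scarcity of X peaks itself, in both lists, remains open. The X-to-autosome density ratio was 0.133 (0.104 to 0.168) in the first 10% of the Sox6 list and 0.306 (0.260 to 0.358) in the last 10%. The Sox9 values were 0.0944 (0.0527 to 0.156) and 0.190 (0.128 to 0.272), with intervals that overlap. That overlap is not a test of their difference, and none was run. A lower X copy number, as males have, could lower both, but the sex of the animals is not given and without scores the deficit that a given copy number would produce is unknown, so it cannot be told apart from a lower density of sites on X. Each list held 5 peaks on chromosome Y, which were not used to infer the sex of the animals. Mappability and gene density on X were not tested.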

How the results depend on the processing

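The excess of overlap over chance kept its direction under all 8 alternatives set before the data were examined, seen from either list (permutation p = 0.001 in each), with folds from 14.5 to 1169. The shares themselves moved by over 1.5 times in 5 cases: to 13.4% of Sox6 and 44.6% of Sox9 peaks with 50% of both peaks required to overlap, to 49.9% and 50.3% at equal list lengths, and to 33.25% of Sox9 peaks for the first 2000 of each list. Shared peaks came earlier in both lists with centres within 250 bp as well, but ordering Sox6 peaks by width gave a difference of 0.68 percentage points in the other direction (permutation p = 0.347), and the cause was not tested, while for Sox9 the difference shrank to -7.67 from -18.3. The count of Sox9 clusters fell to 941 with a gap of 5000 bp, which is 17.2 times chance against 6.18 times before. With a gap of 25000 bp the 8263 Sox6 clusters were fewer than the 10619 of uniform draws, because clusters merge at that gap, while the peaks inside them remained 1.39 times the chance number. The lower overlap of clustered Sox9 peaks turned to 2.05 percentage points higher when a gap of up to 1000 bp was allowed. For Sox6, the difference between clustered and single peaks was -1.49 percentage points within bins of list position and 9.43 with the gap. Both had permutation p = 0.001 in tests that treat peaks as independent, and the cause was not tested. In either list the gap itself favours clustered peaks, since 1 peak of the other list can count for several of them. The comparison of clustered with single peaks and its alternatives were chosen after seeing the data, as were the uses of list order as a rank. Alternatives for promoters, gene lists, peaks per gene and motifs were not run, since no mm9 genome or annotation was used here. No paired analysis was possible because there is 1 sample per group. The unknown depth of both lists limits every statement on peaks without a counterpart, which may be bound below the threshold.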

Other observations

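All patterns in this part were seen before they were tested. Bounds for the tests of list position (of clustered Sox9 peaks and of dense Sox6 clusters) and of neighbouring Sox6 peaks were written before the tests ran, and the other tests were chosen after their results were seen. Dense Sox6 clusters ranged widely in how much Sox9 they held. Over the 137 clusters of 20 or more Sox6 peaks, the shared proportion ran from 0 to 63.6% with a median of 20%. The clusters named next were chosen after their values were seen, except that on chromosome 15. The cluster on chromosome 3 from 113729632 to 113902839 had 103 Sox6 peaks, the third most, and 7 were shared, where the list positions of its peaks gave 14.5 (permutation, adjusted p = 0.373). On chromosome 6 from 52100880 to 52176324, 5 of 65 Sox6 peaks were shared where 14.4 were given by position (permutation, adjusted p = 0.0548). A cluster on chromosome 17 from 45870152 to 45936345 had 12 of 21 shared where position gave 3.99, and the one on chromosome 15 from 97833647 to 97887558 had 14 of 22 where position gave 7.08 (adjusted p = 0.0411 for each, permutation within bins of list position, Benjamini-Hochberg over 137 clusters). Only these 2 clusters, or 1.46%, differed from the number given by list position at an adjusted p of 0.05. That does not show that list position accounts for the shares of the others. The permutations treat peaks of 1 cluster as independent, which they are not.

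The Sox9 peaks that overlapped no Sox6 peak but lay near one may be partly Sox6 sites below the threshold of the Sox6 list, which was not tested on those peaks. The list had not run out of Sox9 sites at its end: the last 5% of Sox6 peaks reached 174 of the 5737 Sox9 peaks that the earlier 95% had missed, against 6.52 ± 2.60 under local shifts (highest of 1000 shifts 15). This count restates the excess already seen in the last 5% of the list. The missed Sox9 peaks were not split by nearness to a Sox6 peak, so the count cannot decide what the near ones are. The first 50% of the Sox6 list had reached 63.6% of the Sox9 peaks. One site called as 2 offset peaks remains open: of the 3271 unshared Sox9 peaks within 1000 bp of a Sox6 centre, 45.4% (43.7 to 47.1) were within 300 bp and 73.4% (71.8 to 74.9) within 500 bp, so the answer depends on the distance chosen. The excess over local shifts for all unshared Sox9 peaks was 16.5-fold within 300 bp and 6.67-fold within 1000 bp, and separate binding at neighbouring sites was not tested.

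Later list position cannot account for the lower overlap of clustered Sox9 peaks, since these came earlier in the list than single ones (median positions 45.6%, 42.9%, 34.5% and 46.6% for clusters of 3 to 4, 5 to 9, 10 to 19 and 20 or more peaks, against 53.2%). Given that order, bins of list position could only be expected to widen the difference, which was -9.70 percentage points within bins and -8.11 without, and without clusters of 10 or more peaks it was -7.46. A candidate explanation is that the Sox9 peaks of a cluster lie beside Sox6 peaks, since the difference turned to 2.05 percentage points with a gap of up to 1000 bp, although a higher density of Sox6 peaks around Sox9 clusters, which was not tested, would have the same effect. Over the 4 clusters of 20 or more Sox9 peaks together, the gap raised the share from 48.0% to 73.5%, still below the 89.7% of single peaks, and the clusters were not tested one by one. No biological explanation was tested.

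The cluster near the end of chromosome X, from 166412440 to 166446723, held 23 Sox6 peaks and 20 of the 245 Sox9 peaks of that chromosome within 34.3 kb. Whether it reflects repeats or sequence shared with chromosome Y in this build was not tested.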
